A study of Mus musculus with 9 samples.

How the data were processed

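Primary hepatic stellate cells from C57BL/6 mice aged 10 weeks were profiled on 9 single-colour Agilent expression arrays, 3 for each of 3 groups. Per the labels' protocols, cells were isolated by collagenase perfusion and plated, and after 7 days of culture were transfected overnight with a control siRNA or an siRNA against Cav1 at 5 nM. RNA was extracted with a mirVana kit and 0.2 µg was labelled with Cy3, per the labels' protocols. The labels give no treatment for the quiescent cells and no time at which they were harvested, and they do not say whether the 3 samples of a group came from separate animals or separate cultures.

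The scans were read with Agilent Feature Extraction 10.7.1.1, per the file headers and the submitters' processing notes. The deposited values used here are processed signals, the intensity of each spot on a linear scale after subtraction of a fitted background and removal of a multiplicative trend, with no scaling between arrays, per the file headers. The deposited table of the whole series holds the same intensity, averaged over the spots of a probe, and served as an alternative. The mean spot intensity, the median local background intensity and the flags for background, saturation and outlier spots were also read from the deposited files. Each array holds 62976 spots, of which 59305 are not controls, for 56605 probes. Probe coordinates are on mm9, per the file headers. No spot was flagged as saturated on any array, and no arrays were copies of each other.

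Gene names came from the files and, for 32994 probes, from the RefSeq accession of the probe looked up in a list of genes of the GRCm38.p6 assembly, which was used for names only. A further 520 probes carried an older name and were renamed through a unique synonym, and 43738 probes then had a symbol found there. Processed signals were put on the log2 scale, the 75th percentile of each array's non-control spots was subtracted, and the spots of a probe were averaged without outlier spots. A probe was kept where at least 0.5 of its spots were well above background on all 3 arrays of at least 1 group, which left 36884 probes, and 67 further probes were left out because every spot was an outlier on an array. The probe with the highest mean signal stood for its gene, giving 23965 genes, 17421 of them with a symbol known to RefSeq. Log2 signals are given relative to the array's 75th percentile.

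The arrays' precision is limited by their number, and for dim genes by background. Probes above background made up 58.4, 51.4 and 58.1% on the quiescent arrays, 61.9, 64.8 and 69.0% on the control-siRNA arrays, and 60.1, 63.2 and 64.0% on the Cav1-siRNA arrays. The arrays sat on 2 slides scanned on 1 day, per the file headers. Slide 1 held the 3 quiescent arrays and control-siRNA array 1, and slide 2 held control-siRNA arrays 2 and 3 and the 3 Cav1-siRNA arrays.

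Each comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes over all 9 arrays with a mean for each group, two-sided), with Benjamini-Hochberg adjustment over the genes of that comparison and calls at an adjusted p under 0.05. Another count also required a log2 change of at least 1. Where a gene's probe was not above background on any array of a group, its change is given as a lower bound, computed against the lowest signal called above background on each array of the lower group, or the gene's own signal there where that was higher. Where the other group did not exceed that level, no bound is given. Tables were read with data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The p-values measure only the spread between these samples, part of which may be technical.

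A set of 41 gene lists (1272 genes, 1211 of them tested) was tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, for lists with at least 5 measured members. The lists covered caveolae, stellate cell quiescence, fibrogenic activation, collagens, collagen processing, matrix proteases and inhibitors, the contractile cytoskeleton, focal adhesions and integrins, YAP, TAZ and SRF targets, TGF-beta and BMP signalling, PDGF and growth factor signalling, retinoid metabolism, cholesterol biosynthesis, and sterol efflux with LXR targets. Others covered fatty acid synthesis with lipid droplets, fatty acid oxidation, glycolysis, oxidative phosphorylation, hypoxia, the cell cycle, p53 and senescence, apoptosis and survival, the interferon response, inflammatory cytokines, NRF2 and oxidative stress, ferroptosis and iron, ER stress, and autophagy with lysosomes. The rest covered Wnt, Notch and Hedgehog, eNOS with endothelin and other vasoactive genes, immediate-early genes induced by tissue dissociation, ribosomal proteins, reference genes, and markers of hepatocytes, macrophages, endothelial cells, cholangiocytes, lymphocytes with neutrophils, mesothelial cells with portal fibroblasts, smooth muscle with pericytes, and erythroid cells.

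The grouping, tests, thresholds, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. By that rule the text names a fixed panel (Cav1, Cav2, Cav3, Acta2, Col1a1, Col1a2, Col3a1, Timp1, Tagln, Lox, Pdgfrb, Lrat, Reln, Des and Pparg). It also names, for each comparison, the 8 largest rises and 8 largest falls among called genes above background on all arrays of both groups with separated groups, and 4 each way for genes below background in a group. For a gene list it names the called members with the largest change, or the members with the smallest adjusted p where none was called. Some genes that the rule picks are not reported here. Genes named outside the rule are said to have been chosen after their values were seen. Des had no kept probe and was not tested.

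The fit was tested on simulated data with 200 changed genes among 23965 in each of 5 draws. With a common spread for all groups, the activation comparison recovered 31.3% of genes changed by a log2 of 1 and 78.2% of those changed by 2, and 5.94% of its calls were false. The figures for the knockdown were 31.3%, 73.3% and 4.62%, and for Cav1 siRNA against quiescent cells 33.4%, 78.5% and 3.35%. With each group's spread as measured, false calls made up 20.4% in the activation, 1.06% in the knockdown and 17.7% in the comparison of Cav1 siRNA with quiescent cells. The alternatives were other background corrections and scalings, filters, probe choices, variance models and array weights, the 2 groups compared alone, the arrays of a single slide, the deposited series table, the slide or the replicate number as a block, and leaving out each array in turn. Scan time coincided with the slide and was not fitted apart from it, and with no saturated spot the filter on saturation changed nothing.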

Results

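Expression was measured in hepatic stellate cells, the retinoid-storing pericytes of the liver that turn into collagen-producing myofibroblasts when activated. The 9 arrays formed 3 groups of 3: quiescent cells, cells activated in culture with a control siRNA, and cells activated in culture with an siRNA against Cav1, the gene of the caveolae coat protein caveolin-1. The arrays gave values for 23965 genes, with 56.0 ± 3.94% (SD, n = 3) of probes above background in quiescent cells, 65.2 ± 3.57% in control-siRNA cells and 62.4 ± 2.07% in Cav1-siRNA cells. Across genes, which are not independent replicates, arrays of quiescent cells correlated with each other at 0.970 to 0.984 and with control-siRNA arrays at 0.705 to 0.719. Control-siRNA and Cav1-siRNA arrays correlated at 0.990 to 0.996, which overlaps the 0.991 to 0.994 seen within the control-siRNA group. The main axis of variation separated quiescent from activated cells and held 92.7% of the variance. The median SD of a gene within a group was 0.35 on the log2 scale in quiescent cells, 0.16 in control-siRNA cells and 0.12 in Cav1-siRNA cells.

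The targeted gene was examined on every array. Cav1, measured by a probe at chromosome 6, 17289414 to 17289473 (mm9), had log2 signals of -4.87, -5.65 and -5.84 on the quiescent arrays, -1.34, -1.12 and -1.09 on the control-siRNA arrays, and -2.87, -2.89 and -3.07 on the Cav1-siRNA arrays. All 3 Cav1-siRNA arrays lay below all 3 control-siRNA arrays, in the direction of their labels, with means of -2.94 ± 0.11 and -1.18 ± 0.14 (SD, n = 3). Cav1 expression after the siRNA was 29.4% of that with the control siRNA (95% confidence interval 20.2 to 42.9%), a log2 change of -1.76 with a standard error of 0.24. That change ranked 8 among all genes by p-value (unadjusted p = 4.8e-05) and missed the threshold after adjustment over all genes (adjusted p = 0.145). It passed when adjusted over the list alone, the 13 caveolae genes (adjusted p = 6.3e-04). Over the alternative settings the log2 change stayed between -1.88 and -1.15 with adjusted p from 8.8e-04 to 0.695, and it was called in 6 of 24. Without quiescent array 1 it was among the calls (adjusted p = 0.021). A second Cav1 probe gave -1.55. Cav2, the partner of caveolin-1 in the caveolar coat, had a log2 change of +0.19 (adjusted p = 0.9998). Cav3, the muscle caveolin, was above background on the control-siRNA arrays alone and was at least 1.11-fold lower after the siRNA (adjusted p = 0.691).

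**Figure D1:**
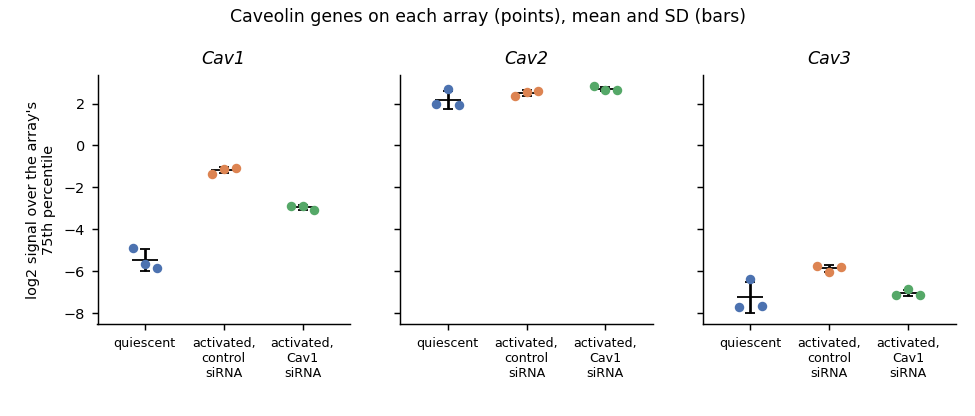
Log2 signal of Cav1, Cav2 and Cav3 relative to each array's 75th percentile, on the 3 arrays of each group (points) with the group mean and SD (bars). Cav1 had means of -5.45 in quiescent, -1.18 in control-siRNA and -2.94 in Cav1-siRNA cells.

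Activated cells with the control siRNA were compared with quiescent cells to show what changed with activation in culture. The quiescent arrays also held high signals of other liver cell types, so the sizes of changes may partly reflect cell content. Genes of the myofibroblast program rose steeply while retinoid-handling genes fell. Acta2, which encodes smooth muscle actin and is the usual marker of activation, rose 330-fold by its brightest probe (log2 +8.37, SE 0.31, adjusted p = 3.3e-08), while its 3 other kept probes gave +9.07, +2.03 and +0.30, so the size of the rise is uncertain. The inhibitor of matrix proteases Timp1 rose 424-fold (log2 +8.73, SE 0.15, adjusted p = 8.7e-10), and the collagen chain gene Col1a1 rose 59.4-fold (log2 +5.89, SE 0.30, adjusted p = 2.4e-07, with +4.77 and +7.08 from its other kept probes). Lrat, the enzyme that stores retinol as esters, fell to background and was at least 103-fold lower (adjusted p = 3.2e-08). Cav1 itself rose 19.3-fold (log2 +4.27, SE 0.24, adjusted p = 4.2e-07), although its probe was above background on only 1 of the 3 quiescent arrays.

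Other members of the fixed panel followed. Col1a2 rose by a log2 of +5.13 (+2.48 to +8.22 from other kept probes), Col3a1 by +3.61 (+6.85 and +7.32 from others), the actin-binding gene Tagln by +5.95, the collagen crosslinker Lox by +10.02 (above background on 1 of the 3 quiescent arrays) and the growth factor receptor gene Pdgfrb by +4.51, with adjusted p at most 4.5e-05. Pparg, a nuclear receptor gene high in lipid-storing cells, had a log2 change of -0.24 (SE 0.29, adjusted p = 0.49), and without quiescent array 2 it was called at -0.62 (adjusted p = 0.0053). The brightest probe of Reln showed no difference (+0.01, adjusted p = 0.98), whereas 2 other kept probes gave -4.18 and -9.73, and normexp background correction moved its value to -5.30. Reln is therefore left without a direction. Cav2 had a log2 change of +0.32 (adjusted p = 0.21), and it was called without quiescent array 2 (+0.57, adjusted p = 0.00505), with the mean of probes (+0.86, adjusted p = 0.0093), with median scaling (+0.47, adjusted p = 0.048) and with array weights (+0.51, adjusted p = 0.038). Cav3 was below background on all quiescent arrays and too dim on the control-siRNA arrays for a bound, so no size or direction is given (adjusted p = 0.0046), and with normexp correction and the 75th percentile its value was -0.38.

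**Figure D2:**
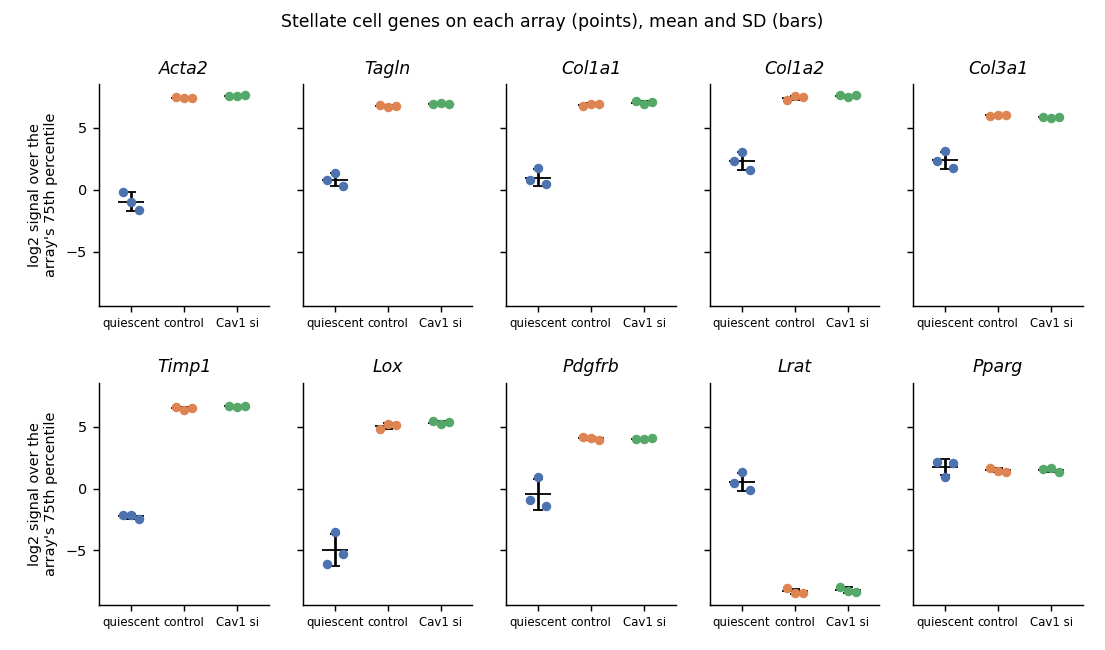
Log2 signal of 10 stellate cell genes relative to each array's 75th percentile on the 3 arrays of each group (points), with mean and SD (bars). Acta2 rose by +8.37 from quiescent to control-siRNA cells, Lrat fell to background, and Cav1-siRNA cells lay within 0.27 of control-siRNA cells for Acta2, Tagln, the collagens, Timp1, Lox and Pdgfrb.

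Among genes above background on every array of both groups, the largest rises were those of the annexin gene Anxa8 (+9.52), the adenylate kinase gene Ak1 (+8.74), Timp1, Col8a1 (+8.51), Ltbp2 (+8.43), Acta2, Epdr1 (+8.27) and Fbln2 (+8.19). Among genes below background in quiescent cells, the BMP antagonist Grem1 was at least 1328-fold higher, Steap1 at least 836-fold, Dlk1 at least 762-fold and the hyaluronan-degrading Cemip at least 422-fold. The largest falls under the same limit were of liver secretory and metabolic genes. Serpina1c had a log2 change of -13.33, Serpina1a of -13.03 and Serpina1b of -12.98, and these near-identical antitrypsin copies are uncertain one by one. Akr1c6 (-12.91), Cyp2e1 (-12.80), Mup20 (-12.68), Inmt (-12.64) and Mup3 (-12.42) also fell. Serpina1d was at least 25168-fold lower, the gluconeogenic Fbp1 at least 17357-fold and Mup21 at least 14782-fold.

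Matrix and contractile genes rose together. Of 30 fibrogenic activation genes 26 rose and 1 fell (median log2 +3.94, camera adjusted p = 1.0e-06, adjusted p = 0.38 with an estimated correlation). Collagens had 25 of 35 rising and 4 falling (median +3.29, or +2.28 with genes below background at their bound and +1.096 under a scaling or background alternative, adjusted p = 0.0017, adjusted p = 0.38 with an estimated correlation). The basement membrane chains Col4a6 (+8.34) and Col4a5 (+8.08) rose, and Col13a1 was at least 620-fold lower. Collagen processing genes rose in 28 of 30 cases and fell in 1 (median +3.05, adjusted p = 6.4e-07, adjusted p = 0.32 with an estimated correlation), led by the lysyl hydroxylase Plod2 (+7.42, above background on 1 of the 3 quiescent arrays) and the chaperone Fkbp10 (+6.81). Among 33 matrix proteases and inhibitors 25 rose and 4 fell (median +2.57, or +2.52 at the bounds and +1.67 under a scaling or background alternative, adjusted p = 4.8e-04, adjusted p = 0.51 with an estimated correlation), with Plat at least 89.4-fold, Mmp3 at least 88.5-fold and Mmp10 at least 55.1-fold higher. In the contractile cytoskeleton 28 of 31 genes rose and 0 fell (median +2.24, adjusted p = 6.4e-07, adjusted p = 0.16 with an estimated correlation), among them Flnc (+8.03). Targets of YAP, TAZ and SRF, transcription regulators that answer to mechanical tension, rose in 27 of 30 cases and fell in 2 (median +2.32, adjusted p = 4.1e-06, adjusted p = 0.27 with an estimated correlation), including Fhl2 (+6.10) and Foxf2 (at least 101-fold higher).

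Caveolae genes also rose, 10 of 13 with 1 falling (median +1.38, or +0.86 at the bounds and +0.76 to +2.02 over the scaling and background alternatives, adjusted p = 0.0085, adjusted p = 0.20 with an estimated correlation), and with the filter on all 9 arrays the list was not called (adjusted p = 0.054). Cav3, left above without a size or direction, is counted among the 10, and the median of +1.38 is its own value. The median of +0.86 at the bounds takes Cav3 as unchanged. Besides Cav1, the coat genes Cavin3 (+6.10) and Cavin1 (+4.06) and the membrane-bending ATPase gene Ehd2 (+5.61) rose. All 49 measured cell cycle genes rose (median +3.46, adjusted p = 1.4e-12, adjusted p = 0.35 with an estimated correlation), among them the mitotic genes Kif20a (+5.98), Cdc25c (+5.34), Tpx2 (+5.03) and Cenpf (+4.99). Markers of mesothelial cells and portal fibroblasts, which could share a culture with stellate cells, stood beside these rises with 11 of 21 rising and 9 falling (median +1.03, or +0.30 under a scaling or background alternative, adjusted p = 0.92), with Wt1 at +7.07 and Krt18 at -10.09.

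Signalling lists were mixed. Focal adhesion and integrin genes had 19 of 34 rising and 7 falling (median +1.12, or +0.57 under a scaling or background alternative, adjusted p = 0.13), with Itga11 at least 224-fold higher and Itga8 at least 166-fold lower. In TGF-beta and BMP signalling 28 of 50 rose and 14 fell (median +0.81, adjusted p = 0.14), with Bmp2 at least 1335-fold lower. In PDGF and growth factor signalling 26 of 42 rose and 13 fell (median +1.61, or +1.50 at the bounds, adjusted p = 0.17), with Fgf7 at least 188-fold higher and Vegfd at +7.89. These 3 lists were called with normexp correction and the 75th percentile (adjusted p = 0.0058, 0.0024 and 0.013), and with an estimated correlation in the main setting they had adjusted p of 0.58, 0.72 and 0.45. Ribosomal protein genes had 35 of 74 rising and 0 falling (32 rising when adjusted over the list alone), with a median of +0.35, against +0.32 for all genes, and adjusted p = 0.0505, and Rpl15 (+1.12) and Rps2 (+1.03) had the largest changes. This list was called in 3 of 5 scaling and background alternatives, and with the slide as a block its median was +0.17 (adjusted p = 0.47).

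Genes of retinoid storage, lipid oxidation and sterol export fell. In retinoid metabolism 19 of 25 fell and 2 rose, or 3 when adjusted over the list alone (median -2.75, or -1.46 under a scaling or background alternative, adjusted p = 6.4e-07, adjusted p = 0.045 with an estimated correlation). The retinol carrier gene Rbp4 (-13.43, above background on 1 of the 3 control-siRNA arrays) and Rarres2 (-7.27) fell, and Rxrg was at least 65.4-fold lower. Stellate quiescence genes fell in 21 of 30 cases and rose in 4 (median -2.89, or -1.24 with the filter on all 9 arrays, adjusted p = 3.0e-06, adjusted p = 0.38 with an estimated correlation), including Colec10 (-8.21), Fcna (at least 690-fold lower) and Abcc9 (at least 96.4-fold lower). Fatty acid oxidation genes fell in 25 of 29 cases and rose in 2 (median -1.93, adjusted p = 1.6e-09, adjusted p = 0.20 with an estimated correlation), with Ehhadh at -7.34 and its regulator Ppara at -6.85. Among sterol efflux and LXR genes 10 of 15 fell and 3 rose (median -4.02, or -0.85 over every kept probe, adjusted p = 0.0012, adjusted p = 0.17 with an estimated correlation), with Apoe at -10.56, Abcg1 at -6.84 and Nr1h3 at -5.90. Fatty acid synthesis and lipid droplet genes had 16 of 35 falling and 6 rising (median -0.38, mean -1.67, the median at -0.23 with median scaling and -0.71 without quiescent array 2, adjusted p = 5.9e-04, adjusted p = 0.057 with an estimated correlation), with Dgat2 (-8.20) and Cd36 (-7.49) falling and Plin5 at least 549-fold lower. Oxidative phosphorylation genes had 28 of 57 falling and 0 rising (median -0.49, or -0.24 with the mean of probes, adjusted p = 6.3e-05, adjusted p = 0.58 with an estimated correlation), led by Sdhb (-1.84) and Uqcrc2 (-1.78). Cholesterol biosynthesis genes had 12 of 25 rising and 6 falling (median +0.64, adjusted p = 0.40, or 0.035 with normexp and the 75th percentile, and 0.58 with an estimated correlation), with Sqle at +4.60. Hepatocyte markers moved with these metabolic groups, since all 38 fell (median -12.19, or -11.82 at the bounds), and 1 of the 38 is also in another list.

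Immune genes and immediate-early genes fell as well. Interferon response genes had 28 of 51 falling and 3 rising (median -0.91, or -1.46 with the slide as a block and -0.60 without control-siRNA array 1, adjusted p = 4.9e-06, adjusted p = 0.51 with an estimated correlation), with Iigp1 at -6.87 and Oasl1 at -6.65. Inflammatory cytokines and chemokines had 24 of 42 falling and 12 rising (median -1.71, adjusted p = 0.0012, adjusted p = 0.51 with an estimated correlation), with Il1b at least 741-fold and Cxcl9 at least 648-fold lower. Immediate-early genes that tissue dissociation induces fell in 24 of 35 cases and rose in 4 (median -1.84, adjusted p = 1.6e-06, adjusted p = 0.32 with an estimated correlation), with Fosb at -8.39, Dusp2 at -7.37 and Zfp36 at -5.60. Macrophage markers moved with these groups, 24 of 27 falling and 3 rising (median -5.40, adjusted p = 2.9e-11, adjusted p = 0.20 with an estimated correlation), and so did lymphocyte and neutrophil markers, 24 of 25 falling (median -6.15, or -6.06 at the bounds and -3.76 under a scaling or background alternative, adjusted p = 2.6e-12, adjusted p = 0.13 with an estimated correlation).

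Markers of every other liver cell type tested were lower in the activated arrays, apart from mesothelial and smooth muscle markers. Hepatocyte markers such as Pck1 (at least 11756-fold) were lower (adjusted p = 1.6e-25, adjusted p = 0.037 with an estimated correlation). All 27 endothelial markers fell (median -9.02, or -8.39 at the bounds, adjusted p = 1.3e-17, adjusted p = 0.18 with an estimated correlation), among them Clec4g (-14.18, above background on 1 of the 3 control-siRNA arrays) and Cdh5 (at least 1025-fold lower). The Kupffer cell genes Clec4f (at least 4000.4-fold) and Vsig4 (at least 591-fold), and S100a9 (at least 727-fold) and Gzmb (at least 656-fold) of neutrophils and lymphocytes, were also lower. All 8 erythroid genes fell (median -7.86, or -6.07 at the bounds and -3.59 under a scaling or background alternative, adjusted p = 1.6e-06, adjusted p = 0.057 with an estimated correlation), with Hba-a1 at -11.97 and Hbb-bt at least 3824-fold lower. Cholangiocyte markers had 7 of 11 falling and 3 rising (median -2.89, or -2.49 at the bounds, adjusted p = 0.049, adjusted p = 0.25 with an estimated correlation), with Krt23 at -6.25, and this list was called in 15 of 23 alternatives, with a median as small as -0.66 under a scaling or background alternative.

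In total 16328 genes were called, 10089 higher and 6239 lower in activated cells, and 11485 of them changed at least 2-fold (6924 higher, 4561 lower). The call of 2668 genes rested on a probe below background in one of the groups. In 69.8% of genes the 3 arrays of a group all lay on the same side of the other group's arrays, where chance gives 10%. The 115 named genes that were called had adjusted p at most 0.0046. Of the calls 61.8% were higher in activated cells, against 46.3% with normexp background correction and the 75th percentile and 61.1% with normexp and quantile normalization. The median change of all genes shifted by -0.44 with normexp and the 75th percentile, by -0.16 with normexp and quantile normalization and by +0.03 with quantile normalization alone, and scaling to the array median shifted it by +0.15. Camera called 25 of 41 lists (8 higher, 17 lower), 2 of them with an estimated correlation, hepatocyte markers and retinoid metabolism, and fry called 41. With normexp and the 75th percentile it called 31 (15 higher, 16 lower) and without a filter 29 (14 higher, 15 lower). Adjusted over the list alone, the member counts were the same in 37 of the 41 lists. Quiescent arrays varied more than the others, and simulated data with these spreads and 200 changed genes gave 20.4% false calls. Far more genes were called here, so that share is not the false share of these calls. With the slide as a block 12559 genes were called, and within slide 1, which sets the 3 quiescent arrays against control-siRNA array 1 with that array assumed to vary like the others, 7615 were called. Both rest on that 1 array as the activated side and give the same changes, so they are a single comparison, in which the 25 lists were called.

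**Figure D3:**
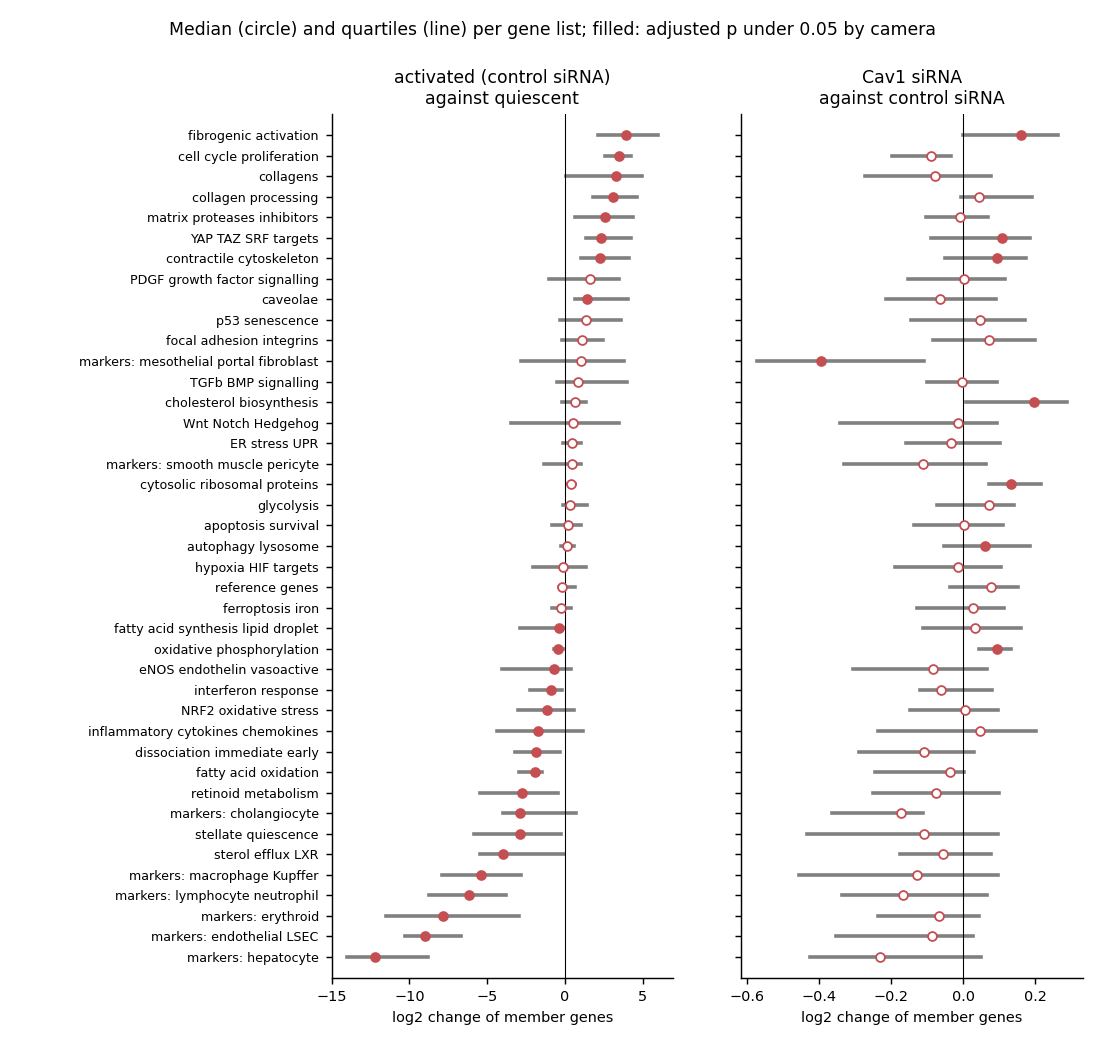
Median log2 change (circle) and quartiles (line) of the member genes of the 41 lists, for control-siRNA against quiescent cells and for Cav1-siRNA against control-siRNA cells. Filled circles mark lists called by camera, 25 in the activation and 8 after the Cav1 siRNA, where medians lay between -0.39 and +0.20 (the ribosomal protein median turned to -0.002 with quantile normalization).

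The Cav1 siRNA was compared with the control siRNA to show what differed with Cav1 RNA at 29.4%, in cells already activated in culture. Caveolin-1 protein was not measured here, and effects of the siRNA on other targets were not tested. The myofibroblast program stayed in place, and the lower genes with small p-values included Igfbp5, Tesc, Slc7a8, Amhr2 and Nprl3 besides Cav1 itself, none of which passed adjustment over all genes. Over the alternative settings Nprl3 and Tesc were called in 7 each, Igfbp5 in 5, and Amhr2 and Slc7a8 in 3 each. Igfbp5, which encodes a secreted binder of insulin-like growth factors, had a log2 change of -1.997 (SE 0.24, adjusted p = 0.097), and the calcium-binding Tesc one of -1.91 (SE 0.23, adjusted p = 0.097). The amino acid transporter gene Slc7a8 was at -1.71 (SE 0.23, adjusted p = 0.145), the anti-Müllerian hormone receptor gene Amhr2 at -1.33 (SE 0.16, adjusted p = 0.097) and Nprl3, a brake on mTORC1 signalling, at -1.16 (SE 0.13, adjusted p = 0.097). Ndufa4l2 was below background on the Cav1-siRNA arrays and was at least 1.78-fold lower (adjusted p = 0.134). All of these were lower on each of 3 arrays, and all but Igfbp5 were chosen after their values were seen.

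The activation markers differed little between the siRNAs. Acta2 had a log2 change of +0.20 (SE 0.31), Tagln of +0.19, Col1a1 of +0.17, Col1a2 of +0.16, Timp1 of +0.16, Lox of +0.27, Col3a1 of -0.15 and Pdgfrb of -0.02, all with an adjusted p of 0.9998. The pooled spread includes the more variable quiescent arrays, so these p-values do not show that the genes were unchanged. Acta2 (control 7.39 to 7.47, Cav1 siRNA 7.61 to 7.63) and Tagln (6.69 to 6.89, 6.94 to 7.01) were higher on all Cav1-siRNA arrays. Col3a1 was lower on all of them (5.99 to 6.04, 5.825 to 5.893). The others overlapped, and chance separates 10% of genes. Other kept probes gave +0.22 to +1.05 for Acta2, -0.16 and +0.29 for Col1a1 and -0.29 to +0.05 for Col1a2. The direction of Pdgfrb turned under median scaling (+0.09) and that of Col1a2 with the mean of its probes (-0.01). Lrat was below background in both groups. Pparg had a log2 change of +0.03 and the brightest probe of Reln one of -0.42, both with an adjusted p of 0.9998. The 2 other kept probes of Reln gave +0.48 and -0.40 but were below background on the activated arrays, so no direction is given for Reln. Caveolae genes other than the caveolins stayed close to the control, with Cavin1 at -0.18 and Cavin3 at +0.15, both chosen after their values were seen, and the list had a median of -0.06 (adjusted p = 0.34), which turned to +0.05 under median scaling.

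Cholesterol biosynthesis genes were slightly higher after the Cav1 siRNA. They had a median log2 change of +0.20, 19 of 25 members lay above 0, and camera called the list (adjusted p = 1.5e-04, adjusted p = 0.38 with an estimated correlation). Nsdhl (+0.49, adjusted p = 0.88) and the sterol carrier gene Stard4 (+0.29) had the smallest p-values in it, and Lss (+0.30), Cyp51 (+0.30) and Sqle (+0.22) lay in the same direction, the last 3 chosen after their values were seen. Mesothelial and portal fibroblast markers were lower, with a median of -0.39, 18 of 21 members below 0 and camera adjusted p = 2.6e-05 (adjusted p = 0.38 with an estimated correlation). Lrrn4 (-1.02), Pi16 (-0.69) and Ly6a (-0.73, chosen after its values were seen) passed when adjusted over the list alone (adjusted p = 0.043 each), against 0 members over all genes (adjusted p = 0.69 each). With camera at the preset correlation both lists were called in each of 25 alternative settings, at adjusted p up to 0.0040 and 1.4e-04. These settings reuse the same arrays and are not independent. By fry in the main setting neither list was called (adjusted p = 0.53 and 0.32).

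Smaller shifts were called for translation and respiration genes. The change varied with brightness, with a median of -0.17 for genes at a control-siRNA level under -4 and +0.06 above 4. Median levels were 6.79 for ribosomal protein, 4.93 for fibrogenic, 4.81 for oxidative phosphorylation and 4.63 for contractile genes. The autophagy list (3.26) and the YAP, TAZ and SRF targets (2.81) were dimmer. Camera compares a list with all other genes, and how far brightness made these calls was not tested. Ribosomal protein genes had a median of +0.13 with 70 of 74 members above 0 (adjusted p = 1.8e-11, adjusted p = 0.88 with an estimated correlation), among them Rpl35 (+0.36) and Rps20 (+0.29), and lost their call and direction with quantile normalization (-0.002). Oxidative phosphorylation genes had a median of +0.09 (adjusted p = 8.1e-05, adjusted p = 0.89 with an estimated correlation), with Atp5b at +0.36 and Ndufa8 at +0.33. The contractile cytoskeleton list had a median of +0.09 (adjusted p = 0.029, adjusted p = 0.75 with an estimated correlation), where Tpm1 was at +0.34 and Synpo2 at -0.64. Fibrogenic activation genes had a median of +0.16 (adjusted p = 0.035, adjusted p = 0.89 with an estimated correlation), with Ccn2 at +0.36 and Actg2 at +0.34. YAP, TAZ and SRF targets had a median of +0.11 (adjusted p = 0.035, adjusted p = 0.88 with an estimated correlation), with Dlc1 at +0.40 and Gadd45a at +0.50. Autophagy and lysosome genes had a median of +0.06 (adjusted p = 0.043, adjusted p = 0.75 with an estimated correlation), with Optn at +0.32 and Gabarap at -0.33. Over the scaling and background alternatives the medians ran from +0.03 to +0.21 for oxidative phosphorylation and +0.01 to +0.20 for contractile genes. They ran from +0.07 to +0.27 for fibrogenic genes, +0.05 to +0.22 for YAP, TAZ and SRF targets and +0.01 to +0.17 for autophagy genes. With quantile normalization these 6 lists lost their calls, leaving cholesterol biosynthesis and the mesothelial markers. Over the 25 alternative settings, ribosomal protein and oxidative phosphorylation genes were called in 23 each and contractile genes in 20. The YAP, TAZ and SRF targets were called in 18, fibrogenic genes in 16 and autophagy genes in 12. With the slide as a block, the fibrogenic list (adjusted p = 0.071) and the autophagy list (adjusted p = 0.071) were not called, and glycolysis (median +0.10, adjusted p = 0.021) and the interferon response (median -0.20, adjusted p = 0.0058) were. With an estimated correlation in the main setting these 2 had adjusted p of 0.63 and 0.94.

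Over all lists, 17 members in 8 lists were lower when adjusted over the list alone, Lrrn4, Pi16 and Ly6a among them, against 0 over all genes. In PDGF and growth factor signalling these were Igfbp5, Fgf18 (-0.80), Igfbp6 (-0.70) and Pdgfb (-0.58), and Cav1 and Cav3 were those of the caveolae list. Rarres2 (-0.71) in retinoid metabolism, Agt (-0.78) among vasoactive genes and Cd5l (-0.94) among macrophage markers passed in the same way. So did the endothelial markers Egfl7 (-1.05, chosen after its values were seen), Robo4 (at least 1.38-fold lower, below background after the siRNA) and Emcn (below background in both groups), and the hepatocyte markers Serpina1a (-0.98) and Cyp2c29 (below background after the siRNA and above it on 1 of the 3 control-siRNA arrays). The macrophage gene Tyrobp had a log2 change of -0.67 (adjusted p = 0.81).

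Over all genes limma called 0 at an adjusted p under 0.05 (smallest adjusted p 0.097). An unadjusted p under 0.05 was reached by 1189 genes, 128 of them higher and 1061 lower, where chance gives 1198 if all groups share a common spread. The number of such genes ran from 746 without control-siRNA array 3 to 4808 with array weights, with 2087 without quiescent array 2, 3242 in the 2 groups alone and 3336 within slide 2. The main fit pooled each gene's spread over all groups, and the median SD was 0.35 in quiescent, 0.16 in control-siRNA and 0.12 in Cav1-siRNA cells. That spread is too wide for a typical gene in the 2 activated groups, so chance would give fewer than 1198. How many fewer was not computed, and the 1189 do not show that no gene changed. The groups were separated in 22.6% of genes, where chance gives 10%, and 98.7% of genes had a log2 change under 1. The number of calls differed between settings. Array weights gave 656 calls (95 higher, 561 lower), the 2 activated groups alone gave 5, or 106 (7 higher, 99 lower) when also fitted with a trend and robust variance, an option chosen after seeing the data, and leaving out quiescent array 1 gave 2, Tesc and Cav1. Camera called 8 lists (7 higher, 1 lower), an estimated correlation 0 and fry 0, and 5 were called without control-siRNA array 3 and 5 without Cav1-siRNA array 2. Simulated changes of a log2 of 1 were recovered in 34.3% of cases with the spreads as measured, so smaller changes were mostly not detectable with 3 arrays a group. With the slide as a block 0 genes were called and Cav1 had a log2 change of -1.84 (adjusted p = 0.363), and within slide 2 it had the same change (adjusted p = 0.115).

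**Figure D4:**
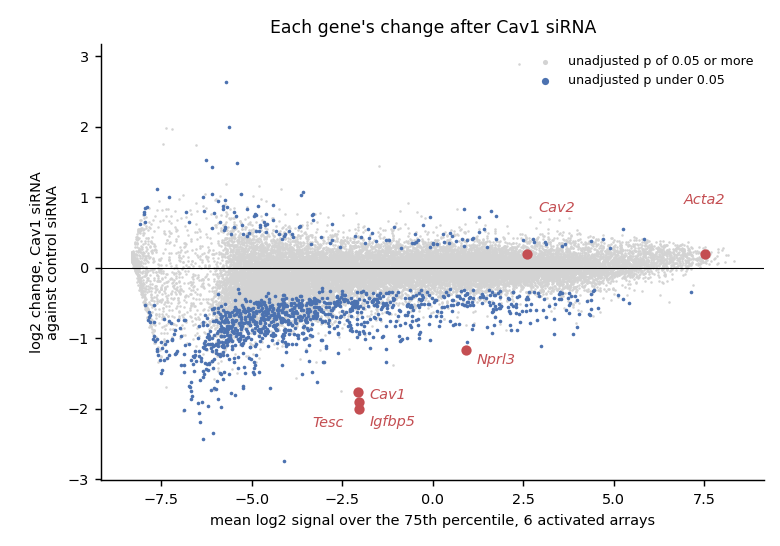
Log2 change of each gene between Cav1-siRNA and control-siRNA cells against its mean log2 signal over the 6 activated arrays, with genes at an unadjusted p under 0.05 in blue and named genes in red. Of the 1189 blue genes 1061 lie below 0, Cav1 lies at -1.76 and Igfbp5 at -1.997.

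Cav1-siRNA cells were also compared with quiescent cells, to show how much of the activation program was present after the siRNA. Acta2 was 8.57 higher on the log2 scale (SE 0.31, adjusted p = 2.7e-08, with +9.37, +2.25 and +1.35 from its other kept probes), Timp1 8.88 higher (SE 0.15, adjusted p = 7.5e-10), Col1a1 6.06 higher (SE 0.30, adjusted p = 1.9e-07) and Lox, above background on 1 of the 3 quiescent arrays, 10.29 higher (SE 0.54, adjusted p = 2.5e-07). Col1a2 (+5.29), Col3a1 (+3.46), Tagln (+6.14) and Pdgfrb (+4.49) rose too, and Lrat was at least 94.2-fold lower. Other kept probes gave +5.06 and +6.92 for Col1a1, +2.19 to +8.27 for Col1a2 and +6.52 and +7.07 for Col3a1. Cav1 was higher than in quiescent cells (log2 +2.51, SE 0.24, adjusted p = 1.5e-05), where its probe was above background on only 1 of the 3 arrays, so the size is uncertain. Cav2 had a log2 change of +0.52 (adjusted p = 0.057) and Pparg of -0.21 (adjusted p = 0.55). Without quiescent array 2 both were called, at +0.76 (adjusted p = 0.0011) and -0.58 (adjusted p = 0.0068), and Cav2 was also called under other settings, among them median scaling (+0.77, adjusted p = 0.0040). The brightest probe of Reln gave -0.41 (adjusted p = 0.28), its 2 other kept probes -3.70 and -10.14, and normexp correction -5.30, so Reln is left without a direction here too. Cav3 was below background in both groups.

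The largest changes resembled those of the activation. Among genes above background on every array of both groups, and besides Timp1 and Acta2, Anxa8 (+9.52), Ak1 (+8.79), Ltbp2 (+8.59), Col8a1 (+8.45), Fbln2 (+8.20) and Epdr1 (+8.06) rose most, and Grem1 was at least 1685-fold, Steap1 at least 909.8-fold, Dlk1 at least 669-fold and Cemip at least 379-fold higher. Among genes above background on every array of both groups, Serpina1c (-13.65), Serpina1e (-12.96), Serpina1b (-12.93), Mup3 (-12.63), Urah (-12.56), Hba-a2 (-12.40), Apoc1 (-12.30) and Gc (-12.25) fell most. Serpina1d was at least 23021-fold, Fbp1 at least 15876-fold and Mup21 at least 13869-fold lower. Fibrogenic genes rose in 26 of 30 cases and fell in 1 (median +3.78, adjusted p = 5.2e-07, adjusted p = 0.36 with an estimated correlation), contractile genes in 28 of 31 with 1 falling (median +2.52, adjusted p = 2.7e-07, adjusted p = 0.14 with an estimated correlation), and all 49 cell cycle genes rose (median +3.29, or +3.27 at the bounds, adjusted p = 1.1e-12, adjusted p = 0.35 with an estimated correlation). Ribosomal protein genes rose in 45 of 74 cases (median +0.54, adjusted p = 0.0012, adjusted p = 0.68 with an estimated correlation), and with the slide as a block this list was not called (+0.27, adjusted p = 0.15). Hepatocyte markers again stood beside the falls, with all 38 lower (median -12.44, or -11.86 at the bounds, adjusted p = 1.4e-24, adjusted p = 0.041 with an estimated correlation).

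In this comparison 16210 genes were called (9687 higher, 6523 lower), 11412 of them at least 2-fold, and the groups were separated in 71.7% of genes, where chance gives 10%. The share of calls that were higher was 59.8%, against 60.1% with normexp and quantile normalization and 45.2% with normexp and the 75th percentile, which shifted the median of all genes by -0.42, and scaling to the array median shifted it by +0.26. Camera called 26 lists (9 higher, 17 lower), or 30 (15 higher, 15 lower) with normexp and the 75th percentile and 31 (15 higher, 16 lower) without a filter, an estimated correlation 2 and fry 41, and member counts adjusted over the list alone were the same in 32 of 41 lists. Of the genes called in both comparisons with quiescent cells, 15126 changed in the same direction and 2 in opposite directions, 1200 were called in the activation alone and 1082 in this comparison alone, and the changes correlated across genes at 0.993. Both comparisons share the quiescent arrays, and unchanged groups correlated at 0.801 on average in 100 simulated draws, with a covariance of 0.11 against an observed 6.90. The draws held no real changes, so the covariances and not the correlations can be compared. No slide held both Cav1-siRNA and quiescent arrays, and with the slide as a block 10141 genes were called (5845 higher, 4296 lower).

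Whether the Cav1 siRNA turned the activation changes back was examined by the direction of each gene in both comparisons. Genes that rose at least 2-fold in the activation had a median log2 change of -0.04 after the Cav1 siRNA, genes that fell at least 2-fold had -0.08, and all genes had -0.04. Among genes brighter than the scaling level these medians were +0.0055, -0.020 and +0.012, and with median scaling that of all genes was +0.08, so their signs are uncertain. With 0 genes called in the knockdown, 0 lay in opposite and 0 in the same direction. With array weights 242 genes were called in opposite directions and 265 in the same direction, where independent lists would share 249 and 180. Both comparisons share the control-siRNA arrays with opposite signs, so unchanged groups correlate negatively, at -0.36 across genes on average in 100 simulated draws. The observed correlation was 0.07. The draws held no activation changes, whose wide range weakens a correlation from shared arrays, so these correlations cannot be set against each other. The covariance was 0.06 against -0.03 simulated, a difference of 0.09, and with disjoint control arrays the correlation was 0.07 and the covariance 0.06.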

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

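The tests within a single slide, the fit of the 2 activated groups with a trend and robust variance, the disjoint controls and the simulated draws for shared quiescent arrays were chosen after seeing the data. The rise of Acta2, Timp1 and the collagen genes Col1a1, Col1a2 and Col3a1 in activated cells with either siRNA, and the fall of Cav1 after its siRNA, kept their direction under every alternative in which the gene was tested (Cav1 was not kept by the filter on all 9 arrays), while the number of genes called after the Cav1 siRNA did not hold. Dim genes are limited by signal over background, and the 3 arrays per group limit all tests.

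For the Cav1 siRNA, against 0 calls (0 at 2-fold or more), normexp with quantile normalization gave 6 calls (3 at 2-fold or more), normexp with the 75th percentile 7 (5), a filter on all 9 arrays 6 (6), the 2 groups alone 5 (5), trend and robust variance 4 (4), array weights 656 (115) and the 2 groups with trend and robust variance 106 (18). Leaving out each array gave 0 to 2 calls, 0 to 2 of them at 2-fold or more. Its 8 called lists became 2 with normexp and quantile normalization, 2 with quantile normalization, 5 without a filter, 5 with the mean of probes, 14 within slide 2, 13 in the 2 groups with trend and robust variance, 0 with an estimated correlation and 0 by fry, and 5 to 10 without an array. Cav1 changed by -1.148 (normexp and quantile, adjusted p = 0.0084), -1.254 (normexp and 75th percentile, 0.0105), -1.875 (array weights, 8.8e-04), -1.764 in the 2 groups alone (0.041, or 0.0030 with trend and robust variance), and -1.842 to -1.70 without an array, with adjusted p from 8.8e-04 to 0.695 over all alternatives. Genes called in opposite directions in the activation and after the siRNA, 0 in the text, numbered 6, 5, 3, 3, 2 and 242 with normexp and quantile, normexp and 75th percentile, the filter on all 9 arrays, the 2 groups alone, trend and robust variance, and array weights, and 0 to 1 without an array. Those in the same direction numbered 2, 3, 2, 2 and 265 with the last 5 of these, and 0 to 1 without an array. In the 2 groups alone the log2 change of Cav1 was the same as in the main fit. Its standard error was 0.11 there, against 0.24 with the spread of the quiescent arrays pooled in. The cause of the other differences was not tested.

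In the activation, the filter on all 9 arrays left 6972 genes changed at least 2-fold, since fewer genes were tested, testing every probe gave 25010 calls (17590 at 2-fold or more), and within slide 1, with fewer samples, 7615 were called (7615 at 2-fold or more). The corresponding values against quiescent cells after the Cav1 siRNA were 7197, 24903 and 17563, and the slide as a block gave 10141. Lists called numbered 2 with an estimated correlation and 41 by fry in both. Leaving out each array gave 14589 to 16823 calls in the activation (11032 to 11620 at 2-fold or more, 23 to 25 lists) and 14495 to 16781 after the siRNA (11127 to 11583, 26 to 27 lists). The share of calls higher in activated cells was 47.0% in the activation and 46.3% after the siRNA without a filter, where the medians of all genes shifted by -0.53 and -0.60.

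Some named genes changed sign, and the cause was not tested. Reln in the activation had -5.18 (normexp and quantile), -5.30 (normexp and 75th percentile), -0.010 (series table), -4.64 (mean of probes), -0.051 (slide as a block and within slide 1) and -0.33 to 0.19 without an array. Pdgfrb after the siRNA had 0.012 (normexp and quantile), 0.018 (normexp and 75th percentile), 0.095 (median scaling), 0.031 (array weights), 0.035 (slide as a block and within slide 2) and -0.066 to 0.035 without an array. Cav3 had -0.38 in the activation and -0.49 against quiescent cells after the siRNA (normexp and 75th percentile), the latter -0.016 to 0.64 without an array. Lrat after the siRNA had -0.0082 with quantile normalization and -0.011 to 0.25 without an array, Col1a2 had -0.014 with the mean of probes, and Wt1 had 0.0013 with median scaling. Pparg had 0.051 (median scaling) and 0.044 (slide as a block) against quiescent cells and -0.58 to 0.011 without an array, and -0.027 to 0.12 after the siRNA without an array. Of 2782 values of the named genes in the activation 2764 kept their side of the threshold and their direction, 4 lost their call, all within slide 1, and 5 gained one. For the Cav1 siRNA 1378 of 1441 held and 50 gained a call, and against quiescent cells 773 of 794 held and 15 gained one.

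Samples of different groups that share a replicate number had residuals that correlated across genes at -0.11 to 0.17, over 0.1 in 1 of 9 pairs, and 2 of 18 comparisons gave the best match to the own number, so the numbers were not taken as a pairing. A replicate block gave 15837 calls in the activation, 0 after the Cav1 siRNA (Cav1 -1.764, adjusted p = 0.413) and 15732 against quiescent cells. Scan time was not run apart from the slide, and leaving out saturated probes removed nothing.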

Other observations

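All tests that weigh explanations in this part were chosen after the result was seen, while the splits of the samples into other groups were set beforehand.

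Several gene groups in the activation have not been described above. Wnt, Notch and Hedgehog genes moved both ways, 22 of 42 rising and 15 falling (median log2 +0.48, or +0.43 at the bounds, adjusted p = 0.75), with the receptor gene Fzd2 at least 284-fold higher, the Hedgehog effector Gli3 at +7.12 and Wnt5a at +6.12. In the p53 and senescence list 16 of 28 rose and 7 fell (median +1.35, adjusted p = 0.13, or 0.0058 with normexp and the 75th percentile, and 0.57 with an estimated correlation), among them the cell cycle inhibitor gene Cdkn2a (+7.94) and Phlda3 (+6.18). Genes of apoptosis and survival had 15 of 37 rising and 15 falling (median +0.18, mean -0.44, the median at -0.06 with the mean of probes, adjusted p = 0.42), with Casp1 at -6.25 and Fasl at least 118-fold lower. NRF2 and oxidative stress genes fell in 24 of 41 cases and rose in 10, or 11 when adjusted over the list alone (median -1.16, adjusted p = 4.0e-04, adjusted p = 0.38 with an estimated correlation), with the glutathione transferase gene Gsta2 at least 514-fold lower and Gpx8 at +5.47. Vasoactive genes of the eNOS and endothelin list fell in 12 of 22 cases and rose in 5 (median -0.74, or -0.46 under a scaling or background alternative and +0.03 over every kept probe, adjusted p = 0.046, adjusted p = 0.51 with an estimated correlation), with the angiotensin receptor gene Agtr1a at least 362-fold lower, and this list was called in 16 of 24 alternatives. Hepatocyte and endothelial markers, with medians of -12.19 and -9.02, moved with these falls.

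In other metabolic and stress lists members moved both ways. Glycolysis genes had 11 of 25 rising and 4 falling (median +0.29, adjusted p = 0.45, or 0.043 with normexp and the 75th percentile, and 0.55 with an estimated correlation), with Eno2 at +5.42 and Aldoc at -4.93. Hypoxia targets had 11 of 27 rising and 11 falling (median -0.15, which turned to +0.001 under a scaling alternative, adjusted p = 0.42), with Loxl2 at +4.07 and Bnip3 at -3.74. Ferroptosis and iron genes had 5 of 23 rising and 10 falling (median -0.24, adjusted p = 0.13), with the iron exporter gene Slc40a1 at -5.69. In the ER stress list 17 of 33 rose and 8 fell (median +0.45, mean -0.01, adjusted p = 0.54), with Asns at +4.22 and Atf3 at -5.83. Autophagy and lysosome genes had 13 of 43 rising and 9 falling (median +0.15, adjusted p = 0.92), with Ctsk at +4.74. Smooth muscle and pericyte markers had 5 of 13 rising, or 6 when adjusted over the list alone, and 4 falling (median +0.43, mean -0.07, -0.16 under a scaling alternative, adjusted p = 0.92), with Actc1 at +6.75 and Cnn1 at +5.44, and 7 of the 13 are also in another list. Reference genes had 5 of 15 rising and 3 falling (median -0.21, mean +0.10, +0.19 under a scaling alternative, adjusted p = 0.71), with Polr2a at +1.62 and Ywhaz at +1.04.

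Markers of most other liver cell types were far higher in quiescent than in activated arrays. The hepatocyte list had a median quiescent log2 level of 6.567, and the lowest of 5 such lists, lymphocytes and neutrophils, had 1.279, which is consistent with RNA of several cell types in the quiescent samples, a candidate source of many falls in the activation. Cholangiocyte markers, outside these 5 lists, lay at -3.485. Array scaling as the cause is argued against by the size of the fall. The 5 scaling and background alternatives shifted the median of all genes by -0.44 to +0.15, while the smallest fall of the hepatocyte median over them was -9.148. Constant shifts of that size could not have removed the fall, so its survival under them is no separate test. Loss of such transcripts by the stellate cells themselves during culture cannot be told apart from loss of other cells, since the design changes both together, and 17 of 38 hepatocyte markers stayed above background on all control-siRNA arrays. The labels name no sort that would remove other cells, and which of these falls belong to stellate cells stays open. RNA of other cells would also leave a smaller share of stellate RNA in the quiescent samples. The sizes of the rises are therefore uncertain too, and this was not tested.

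Of the genes with an unadjusted p under 0.05 after the Cav1 siRNA, 89.2% were lower. Differences between single arrays may account for the lean, but the splits cannot decide this. Another split of the same 6 arrays gave 95.6% in one direction, over 495 genes. It kept control-siRNA arrays 1 and 3 together, so a real lowering could enter it, and it is no measure of chance. Without such a measure, scaling as the whole cause (74% with quantile normalization, 71% with median scaling, 69.4% with normexp and quantile normalization) and dim probes as the whole cause (84.8% among genes brighter than the scaling level) cannot be told apart from other causes. The share was 87.9% with the slide as a block and 64.5% within slide 2 (2153 lower, 1183 higher). An effect of caveolin-1 on many genes stays open.

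Mesothelial and portal fibroblast markers were lower after the Cav1 siRNA, and the highest camera adjusted p over 5 scaling and background alternatives was 7.734e-05. Camera compares a list with all other genes, so a constant shift of an array, as in median scaling, could not remove the call. Quantile normalization and normexp correction could have, and their calls argue against such processing as the whole cause. The median nevertheless shrank from -0.39 to as little as -0.14 under one of the 5 alternatives. Fewer such cells in the Cav1-siRNA cultures may be a cause, and this cannot be told apart from a change within stellate cells. The 10 members brighter than the scaling level spanned a range of 1.14, from -1.02 to +0.12, and 2 of the 21 members are also in another list. The mesothelial surface genes Upk3b (-0.57), Gpm6a (-0.53), Upk1b (-0.50) and Msln (-0.39), chosen after their values were seen, lay on the lower side with Lrrn4 (-1.02), while the other 5 of the 10 lay between -0.11, for Wt1 (SE 0.15), and +0.12. A change of gene expression through caveolin-1 was not tested apart from cell content.

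The 10 splits of 6 arrays into 3 against 3 are too few for a share under 0.05. Each split other than the real one mixes the groups unequally and keeps part of any real difference, so its counts are no measure of chance. The real split gave 16328 genes and 25 lists in the activation (highest of the other splits 0 and 24), 0 genes and 8 lists after the Cav1 siRNA (0 and 3), and 16210 genes and 26 lists against quiescent cells (0 and 23). A count as large came from 1 split for each of these, and from 10 for the genes after the Cav1 siRNA.

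Of 8189 genes with several kept probes, 525 (6.41%) had probes called in opposite directions in the activation, and 3871 had all probes called in the same direction.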
